A study of Mus musculus with 2 samples.

How the data were processed

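Acetylation of histone H3 at lysine 27 (H3K27ac), a chromatin mark of active promoters and enhancers, was measured by chromatin immunoprecipitation followed by sequencing in mouse heart at embryonic day 15.5. The samples were 2 biological replicates of 1 group, strain B6NCrl with both sexes pooled. Replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62 embryos. The labels give a fragment size range of 300 to 500 bp. There was no second condition, so no contrast between conditions and no paired analysis was possible, because the series holds a single group.

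The authors deposited 4 peak lists on mouse genome build mm10: 1 per replicate, 1 from both replicates pooled, and 1 of replicated peaks. The deposited records state that the replicated list was derived from the pooled list and both replicate lists. They also name 1 further input file for each replicate list, which they do not describe. The lists were used as deposited. Each deposited list gives a score, used here for nothing, and a signal value. The sources do not name its unit, and it was taken to be the authors' fold enrichment over control from the layout of the files. Every fold given here, the fold of at least 4 and the ranking of domains rest on that reading. Per the file headers and layout, the deposited lists also give the p-value and the q-value of each peak, both as -log10, and the offset of the summit. The peak caller, its settings and the sequencing depth are not given in the sources used here, and the lists hold no counts. Depth is therefore unknown, and no interval or limit that needs it is given. The authors' fold values were used to describe, rank and filter peaks within a list. For named genes they were also set side by side between lists, but no difference was tested or read as a change.

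Peaks on the 21 chromosomes were used for all comparisons, and those on unplaced sequence were left out. Genes and start sites came from GENCODE M21 and sequence from the GRCm38.p6 assembly, the same build as the lists. As a check of the build, 0 peaks of the 4 lists reached into unsequenced parts of the chromosomes. Gene results used 21884 protein-coding genes with a unique symbol. A transcription start site (TSS) peak of a gene was a peak whose interval reached within 1 kb of any annotated TSS of that gene, and its fold was that of the highest such peak. The summit of such a peak can lie farther away. TSS folds and widths are therefore those of the whole peak and not of the start itself. A peak was counted for every gene whose window it reached, so neighbouring genes can share a TSS peak. Coordinates are 1-based.

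A peak of a replicate was called shared when at least 50% of its length was covered by peaks of the other replicate. The share was compared with 1000 random circular shifts of the peaks along each chromosome, one-sided. Each replicated peak was placed by its summit at a promoter (within 1 kb of a TSS of any gene), in an exon, in an intron or between genes, and compared with 1000 shifts, two-sided. Intervals for shares are 95% Wilson intervals and cover counting error only. Odds ratios of promoter location carry 95% intervals, with no p across peaks, since peaks are not replicates.

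The lists of genes were fixed before the data were examined, as were the tests, the thresholds, the motifs and the alternatives, apart from those named as later choices. There were 27 lists with 612 genes, of which 608 matched a symbol of the annotation. They cover the sarcomere, cardiac transcription factors, natriuretic and secreted factors, calcium handling and ion channels, fatty acid oxidation and mitochondrial energy metabolism, glycolysis, endothelium and endocardium, epicardium, fibroblasts and valve mesenchyme, smooth muscle and pericytes, ribosomal proteins, the cell cycle, and signalling by retinoic acid, Notch, BMP and Hippo. Other lists cover tissues and cells outside heart muscle, namely erythroid cells, myeloid cells, T cells and thymus, lung and airway epithelium, hepatocytes, skeletal muscle, neurons, neural crest, kidney, gut and pancreas, epidermis, pluripotency and germ line, and anterior and posterior Hox genes.

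The share of each list with a replicated TSS peak was compared with all other protein-coding genes by a two-sided Fisher exact test. Odds ratios of lists had 0.5 added to each cell. The length covered by replicated peaks from 50 kb before to 50 kb after each gene was averaged per list and compared with 10000 random lists matched on gene length in 10 bins, two-sided. The smallest p these random lists can give is 0.0002. Genes with a TSS peak in only 1 replicate were tested per list by an exact two-sided binomial test against the split over all other genes. Distal peaks, with summits over 2.5 kb from any TSS, were stitched into domains when within 12.5 kb and ranked by summed width times fold. Each domain was given the gene whose TSS was nearest to the middle of the domain. List members among genes nearest to the top 5% of domains were compared by a two-sided Fisher exact test with genes nearest to other domains. All p-values of a family were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05.

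For motifs, the 500 bp around the summit of each distal replicated peak were searched for 16 consensus motifs on both strands. They were compared with windows 5 kb to each side that met no pooled peak. The log2 ratio of the 2 shares was ranked among 100 rearrangements of the same letters, one-sided, and the smallest p this allows is 0.0099.

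Named genes followed a rule fixed before the data were examined. It took a set list of heart, blood and other tissue genes, and for each list the 2 members with the highest TSS fold and up to 2 members without a TSS peak, in alphabetical order. It also took the gene nearest to each of the 15 largest domains. The rule gave 133 genes. Any gene outside it is said to have been chosen after its values were seen.

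The steps were tested on simulated data. With 60% of the peaks of a 100551-peak list copied, 100% of the copied peaks and 60.6% of all peaks were called shared. Of lists raised or lowered at promoters, 97% and 97% were recovered, and 1.47% of unchanged lists were called. Of lists with neighbourhood coverage raised 2.5 times, 59% were recovered, and 0.526% of unchanged lists were called. A planted list with peaks in 1 replicate only was called, with 0 others. Every member of that list was given a peak in replicate 2 only. In the data no list had more than 6 single-replicate genes, so this call does not show what the test could find there. All 5 planted motifs were called, with 0 others, on 4630 windows. The 5 were planted together, and a call needs several motifs at the smallest p. The simulation therefore does not show that a motif planted alone would be called.

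Alternatives were a -log10 q of at least 5, a fold of at least 4, other overlap rules, other promoter windows, protein-coding TSSs alone, other flanks, distal peaks alone, other stitching and ranking, other motif windows, equal numbers of peaks, the pooled list, and each replicate alone. There were 2 more, chosen after seeing the data: 50% of the replicated peak itself as the overlap rule, and 1 gene per locus, where list members with overlapping windows of 50 kb each side were counted once. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.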

Results

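H3K27ac was profiled in 2 biological replicates of mouse heart at embryonic day 15.5, a stage when the chambers are formed and the heart muscle is still growing. The replicate 1 list held 100551 peaks on chromosomes and covered 66.9 Mb, and the replicate 2 list held 114436 peaks and covered 72.1 Mb. The pooled list held 116499 peaks over 86.9 Mb and the replicated list 71489 peaks over 74.98 Mb. Median peak widths were 376, 356, 414 and 721 bp in the order replicate 1, replicate 2, pooled and replicated. The highest signal value, taken from the file layout to be the authors' fold enrichment, was 58.0, 56.1, 63.3 and 63.3 in the same order. Sequencing depth was unknown. The labels name no contrast, so the comparisons are replicate against replicate, and then the genes and sequences at which the replicated peaks lie.

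Most marked start sites were marked in both pools. Of 21884 protein-coding genes, 12309 had a TSS peak in both replicates, 306 in replicate 1 only and 629 in replicate 2 only. Myh7, the beta myosin heavy chain of fetal ventricle, had a TSS fold of 31.3 in replicate 1 and 31.7 in replicate 2. Gata4, a zinc finger factor of heart muscle development, had 22.4 and 24.2, and Mef2c, a factor of muscle differentiation, had 20.8 and 21.1. Not all pairs were as close: Tbx20 had 24.4 and 16.5, and the potassium channel gene Kcnh2 had 32.2 and 20.6. Many of the set heart muscle genes were higher in replicate 1, such as Nkx2-5 (19.2 and 14.9), Hand2 (28.5 and 21.3), Tnnt2 (21.5 and 17.5) and Ryr2 (14.9 and 9.81). Myh6, Nppa and Nppb were higher in replicate 2, as were Myh7, Gata4 and Mef2c. With depth unknown, no change between the pools is read from these folds. Across all peaks, 64.6% of replicate 1 peaks (64957; 95% interval 64.3 to 64.9) were shared with replicate 2. Conversely, 55.7% of replicate 2 peaks (63739; 55.4 to 56.0) were shared with replicate 1. Random shifts gave 2.85% and 2.67% on average and at most 3.40% and 3.54% (one-sided permutation p = 0.001 for each, the smallest that 1000 shifts can give). Shared peaks held 83.8% and 77.9% of the covered sequence of the replicates.

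Sharing followed peak strength within each list. In the strongest 10% of peaks by fold, 99.96% of replicate 1 and 99.9% of replicate 2 peaks were shared, against 38.4% and 27.7% in the weakest 10%. Shared peaks of replicate 1 had a median fold of 4.37 and a median width of 558 bp, against 2.97 and 249 bp for the others. In replicate 2 these values were 4.53 and 576 bp against 2.95 and 252 bp. Under other overlap rules and peak thresholds the shares of the 2 replicates were 41.3% to 77.6%.

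**Figure D1:**
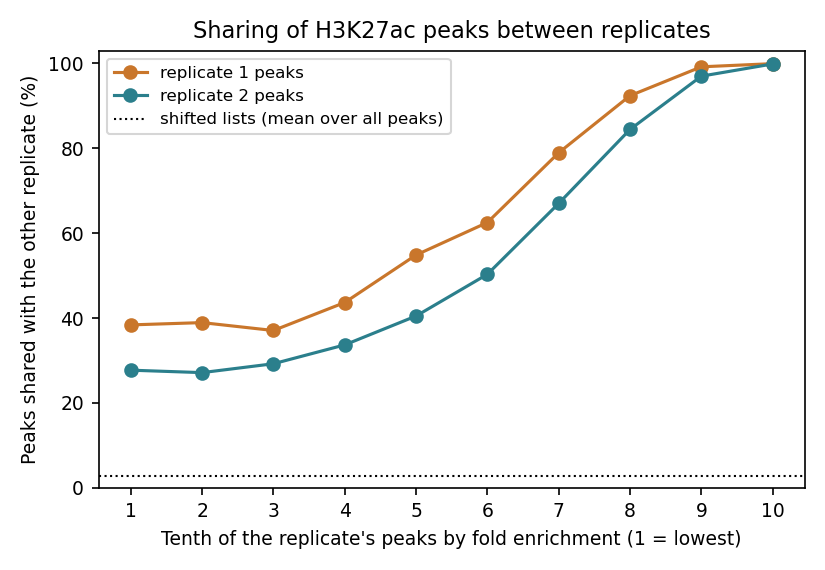
Percent of peaks of each replicate that were shared with the other replicate, in 10 equal classes of fold enrichment from weakest to strongest, with the share given by random shifts. Sharing was 38.4% and 27.7% in the weakest class and 99.96% and 99.9% in the strongest.

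The replicated list kept the stronger part of the pooled list. All 71489 replicated peaks were present in the pooled list by coordinates, 61.4% of its peaks (95% interval 61.1 to 61.6) and 86.3% of its covered sequence. Replicated peaks had a median fold of 4.16 and a median width of 721 bp, against 2.47 and 236 bp for the 45010 pooled peaks left out. Of the replicated peaks, 61484 (86.0%) overlapped a peak in both replicate lists by at least 50% of either peak. The other 10005 did not, of which 3851 were found in replicate 1 only, 5882 in replicate 2 only and 272 in neither. Their median fold was 2.96, against 4.59 for those found in both. Of the 45010 pooled peaks left out, 0 met that overlap in both replicate lists, so every pooled peak that met it was kept. The rule by which the 10005 entered is not given in the sources used here. With at least 50% of the replicated peak itself required, a rule chosen after seeing the data, 72.5% of replicated peaks were found in both and 19648 were not. With peaks of -log10 q of at least 5 alone in every list, 56.6% were found in both replicates. That threshold kept 84.4% of replicated peaks but 46.3% of replicate 1 and 42.7% of replicate 2 peaks. The lower share therefore does not show that stricter peaks were less often replicated. Under that threshold 93.5% of the pooled peaks were in the replicated list, and 99.9% with a fold of at least 4.

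Promoters were the locations most enriched for replicated peaks. Of the 71489 peaks, 19237 (26.9%; 95% interval 26.6 to 27.2) had their summit within 1 kb of a TSS, 4.25 times the 6.33% given by shifts. Introns held 46.2% against 40.3%, exons 4.10% against 3.39%, and the sequence between genes 22.8% against 49.99% (two-sided permutation p = 0.002 for each, the smallest that 1000 shifts can give). Promoter peaks had a median fold of 7.65, against 3.74 in exons, 3.74 in introns and 3.85 between genes. With a fold of at least 4, the exon share was 3.30% and no longer passed (permutation p = 0.607, range over alternatives 0.00995 to 0.607), and the intron share was 38.0%, below its shifts. Promoters took 29.8% of shared and 11.9% of unshared replicate 1 peaks (odds ratio 3.15, 95% interval 3.04 to 3.27), and 30.0% and 13.5% of replicate 2 peaks (2.75, 2.66 to 2.83). With promoter windows of 2.5 kb the replicate 1 odds ratio was 2.08.

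Start sites of heart muscle genes were marked almost without exception. Here and below, a gene with or without a peak is one with or without a replicated TSS peak, unless a replicate is named. All 28 sarcomere genes had a replicated TSS peak, including Cryab, a chaperone of muscle fibres, with a fold of 40.6, and Tpm1, the thin filament tropomyosin, with 38.0. Myh7 had 37.0, the cardiac actin gene Actc1 28.8, the inhibitory troponin gene Tnni3 20.1, the ventricular light chain gene Myl2 19.2, the troponin T gene Tnnt2 15.2, the alpha myosin gene Myh6 15.2, and the atrial light chain gene Myl7 10.3. Of 29 cardiac transcription factors, 28 had a peak, led by Mef2d at 48.3 and Mef2a at 46.4. Hand2 had 23.1, Mef2c 23.2, Gata4 20.9, Tbx20 20.5, Nkx2-5 18.8 and Tbx5 16.5, all regulators of chamber formation. Isl1, a factor of early cardiac progenitors, had no replicated TSS peak and a fold of 3.39 in replicate 2 only. Of 26 calcium handling and ion channel genes, 25 had a peak, with the connexin gene Gjc1 at 35.4, the potassium channel gene Kcnh2 at 32.1, the calcium pump regulator Pln at 19.5 and the calcium release channel Ryr2 at 13.7. Hcn1, a pacemaker channel gene, was the only member of that list without one.

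Genes of energy, growth and signalling were marked as widely. Promoters of housekeeping genes, such as those of ribosomal proteins, are acetylated in every tissue. A high promoter share therefore does not by itself set heart genes apart. All 25 genes of fatty acid oxidation and mitochondrial energy metabolism had a TSS peak, led by the acyl-CoA dehydrogenase gene Acadl at 46.8 and the ADP/ATP carrier gene Slc25a4 at 40.2. All 19 glycolysis genes had one, led by Pfkm at 36.3 and Pkm at 35.8, as did all 30 ribosomal protein genes, led by Rpl7 at 46.6 and Rpl10a at 23.1. Of 28 cell cycle genes, 27 had a peak, with Cdk2 at 28.9 and the cyclin gene Ccnd3 at 27.8, and Bub1 had none. Of 26 signalling genes, 25 had a peak, with the BMP inhibitor Smad7 at 40.5 and the Notch target Hes1 at 36.6, and the retinoic acid synthesis gene Aldh1a2 had none.

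Start sites of the other cell types of the heart were also marked. Endothelial and endocardial genes had a peak in 29 of 31 cases, with the adhesion genes Pecam1 at 16.7 and Cdh5 at 6.51 and the receptor modifier Ramp2 at 16.7. The Pecam1 peak (chromosome 11, 106657454 to 106662853) met an annotated start near the far end of this minus-strand gene. It lay far from the outermost start at 106750628. Etv2 and Vwf had none. Fibroblast and valve genes had one in 23 of 24 cases, with the matrix genes Vcan at 23.0, Col5a2 at 14.97 and Col1a1 at 7.70, and Thy1 had none. Smooth muscle and pericyte genes had one in 15 of 18 cases, with Smtn at 32.2, Des at 29.2 and Acta2 at 12.1, while Kcnmb1 and the smooth muscle myosin gene Myh11 had none. Compared with the 57.1% of all genes that had a TSS peak, these 11 lists were higher by two-sided Fisher exact tests. Adjusted p over 27 lists ranged from 7.57e-07 for ribosomal proteins through 1.67e-06 for the sarcomere to 0.0386 for smooth muscle. The smooth muscle call was lost with replicate 2 alone (odds ratio 3.06 against 3.33), with replicate 1 alone (2.37) and under 2 further alternatives (adjusted p 0.00411 to 0.118 over 7 alternatives).

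Epicardial and natriuretic genes did not pass, in lists too small to exclude a difference. Of 16 epicardial genes, 9 had a peak (Fisher exact test, adjusted p = 1), with Tcf21 at 10.7, Tbx18 at 10.5 and Wt1 at 7.05, all regulators of the epicardium, and with Aldh1a2 and C3 lacking one. Of 12 natriuretic and secreted factor genes, 9 had a peak (75%, 95% interval 46.8 to 91.1; odds ratio 2.04; Fisher exact test, adjusted p = 0.275), with the growth factor genes Igf2 at 25.7 and Vegfa at 24.3. Nppa, the atrial natriuretic peptide gene, had a fold of 3.81 and Nppb 8.91, while Fgf16 and Nppc had none.

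Genes of other tissues mostly lacked a replicated TSS peak. Only 1 of 32 neuronal genes had one (Elavl4 at 7.99; Fisher exact test, adjusted p = 2.03e-09), with Neurod1, Dcx and Dlx1 lacking it. So did 1 of 21 gut and pancreas genes (Cpa1 at 3.55; 3.06e-06), with Cdx1 and Cdx2 lacking it, and 0 of 17 posterior Hox genes, including Hoxa10 and Hoxa11 (3.06e-06). Hepatocyte genes had one in 3 of 22 cases (7.30e-05), with Foxa3 at 8.37 and Trf at 4.66, and none at Alb, Afp or Ahsg. Kidney genes had one in 2 of 18 cases (0.000191), with Eya1 at 9.62 and Slc12a3 at 8.32, and none at Aqp2 or Cubn. Pluripotency and germ line genes had one in 3 of 21 cases (0.000136), with Esrrb at 8.95 and Dazl at 5.87, and none at Pou5f1, Ddx4 or Dppa2. Epidermal genes had one in 4 of 18 cases (0.00521), with Krt10 at 28.7 and Perp at 7.98, and none at Krt5, Dsc1 or Dsg1a.

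Blood genes were low as well, by replicated peaks. Erythroid genes had a TSS peak in 4 of 21 cases (Fisher exact test, adjusted p = 0.000884), with the transferrin receptor gene Tfrc at 25.5 and the spectrin gene Sptb at 23.6. Hba-a1, an alpha globin gene, Alas2 and Epb42 had none. Myeloid genes had one in 6 of 22 cases (0.0109), with Laptm5 at 4.82 and Spi1 at 3.71, and no replicated one at Csf1r, Adgre1 or Aif1. Aif1 had a TSS peak in each replicate list nonetheless (2.74 and 4.31), as did the T cell gene Cd247 (3.59 and 2.47), and Csf1r in replicate 2 (2.68). T cell and thymus genes had one in 5 of 20 cases (0.00763), with the T cell factor Bcl11b at 7.10 and the kinase gene Lck at 6.34, and no replicated one at Ccr9 or Cd247. Skeletal muscle genes had one in 11 of 29 cases (0.0494), with Mylpf at 18.1 and Casq1 at 16.6, and none at Myod1, Acta1 or Atp2a1. Lung genes had one in 8 of 21 cases (0.135), with Hopx at 27.6 and Id2 at 23.9, and no replicated one at Nkx2-1, Cldn6 or Epcam. Neural crest genes had one in 7 of 19 cases (0.121), with Hand2 at 23.1 and Mitf at 21.4, and none at Sox10, Fabp7 or Foxd3. Anterior Hox genes had one in 7 of 15 cases (0.461), with Hoxa1 at 8.58 and Hoxb2 at 8.01, and no replicated one at Hoxa3 or Hoxb1. These Hox genes lie in 4 clusters, so neighbours share peaks and their p treats linked genes as separate, as it does for posterior Hox genes.

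The T cell call depended on the peaks used. It was lost under 3 of 7 alternatives, with odds ratios of 0.837 for replicate 2 alone, 0.549 for the pooled list and 0.386 for promoter windows of 2.5 kb, against 0.267 (adjusted p 0.00157 to 0.886). Lung genes had an odds ratio of 1.10 with replicate 2 alone, and passed with replicate 1 alone at 0.380 and with a fold of at least 4 at 0.379 (0.0355 to 1 over 7 alternatives). Neural crest genes passed with replicate 1 alone at 0.278 and with promoter windows of 500 bp at 0.294 (0.0118 to 0.199). The myeloid call was lost with each replicate alone (8.83e-06 to 0.149) and under 2 further alternatives, and the skeletal muscle call under 3 of 7 (0.0287 to 0.0757). The skeletal muscle odds ratio stayed between 0.413 and 0.497, against 0.467. Neighbouring genes can share a peak, so a marked start site in a list is not always that of its member alone.

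**Figure D2:**
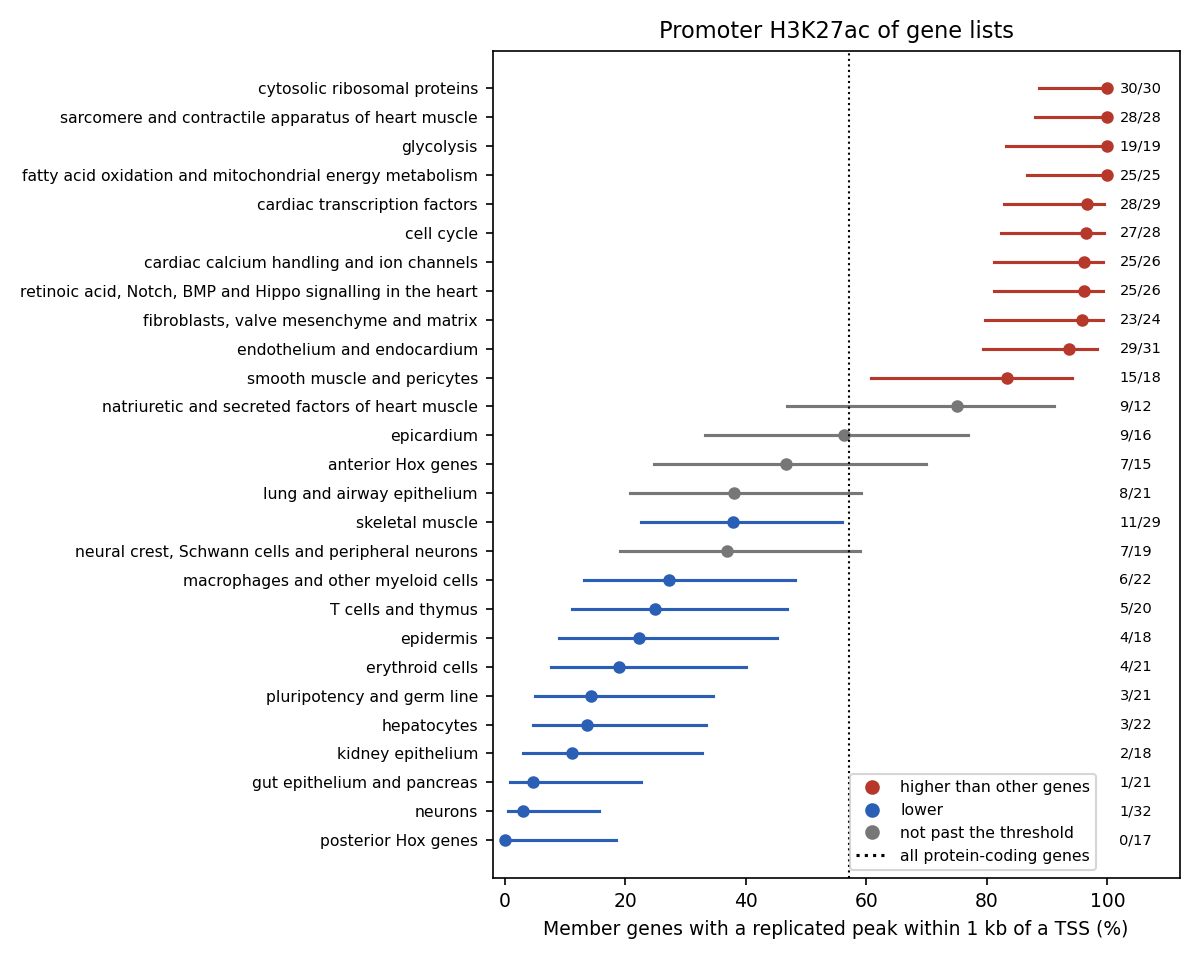
Percent of member genes with a replicated TSS peak for each of the 27 gene lists, with 95% Wilson intervals and counts, and the share among all protein-coding genes as a line. Heart lists lie above the 57.1% of all genes, apart from epicardium at 9 of 16 genes. Lists not particular to heart, such as ribosomal proteins, glycolysis and the cell cycle, lie above it too, and lists of other tissues lie below it.

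Sequence around heart muscle genes was far more acetylated than around other genes of like length. From 50 kb before to 50 kb after each gene, sarcomere genes had a mean of 30.3 kb covered by replicated peaks (SD 17.0 over 28 genes), 3.64 times the 8.34 kb of random lists. Gata4 had 75.6 kb, Myh6 63.5 kb, Myh7 58.3 kb, Nkx2-5 44.5 kb, Ryr2 43.8 kb, Tnnt2 41.6 kb, Tbx5 40.5 kb and Pln 20.3 kb. Cardiac transcription factors had a mean of 26.99 kb (3.07 times random), signalling genes 26.4 kb (2.89 times) and calcium and ion channel genes 26.0 kb (2.58 times). Glycolysis genes had 15.9 kb (2.11 times), endothelial genes 17.5 kb (2.08 times), anterior Hox genes 12.48 kb (1.95 times), fatty acid oxidation genes 14.4 kb (1.84 times) and ribosomal protein genes 10.6 kb (1.75 times). Neuronal genes had 2.51 kb (0.307 times random), pluripotency and germ line genes 2.31 kb (0.318 times), kidney genes 3.87 kb (0.438 times) and posterior Hox genes 0.968 kb (0.161 times).

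By permutation over 27 lists, adjusted p was 0.0018 for the sarcomere, cardiac factors and neurons, resting on the smallest p that 10000 random lists can give. It was 0.0027 for pluripotency, 0.00324 for posterior Hox genes, 0.0054 for signalling, 0.00926 for calcium and ion channels, 0.0108 for glycolysis, 0.0144 for endothelium, 0.0157 for anterior Hox, fatty acid oxidation and ribosomal genes, and 0.0266 for kidney. Not passing were smooth muscle (1.72 times random) and cell cycle (1.53 times) at 0.0634 each, hepatocytes (0.560) at 0.0736, epidermis (0.519) at 0.0743, fibroblasts (1.44) at 0.139 and skeletal muscle (1.34) at 0.192. Also not passing were T cells (0.761) at 0.471, epicardium (0.811) and gut (0.846) at 0.715 each, neural crest (1.08) at 0.824, lung (0.919) at 0.891, erythroid (0.925) at 0.919, natriuretic factors (0.896) at 0.932 and myeloid cells (0.955) at 0.953. The members of the Hox lists share flanks within their clusters. With 1 gene per locus, an alternative chosen after seeing the data, 4 anterior genes were left at 1.38 times random (permutation test, adjusted p = 0.615) and 4 posterior genes at 0.290 times (permutation test, 0.382). Neither Hox call was kept, and 8 lists were higher and 3 lower. The posterior Hox ratio was 0.281 with replicate 2 alone and 0.092 with replicate 1 alone. The anterior Hox call also rested on replicate 2: without it the ratio was 1.14, and with distal peaks alone it was 0.601. Smooth muscle, cell cycle and hepatocyte genes passed with replicate 2 alone (ratios 1.78, 1.54 and 0.535), and hepatocyte and gut genes with flanks of 10 kb (0.303 and 0.328). Distal peaks alone left 5 lists higher and 2 lower. Calls lost there were glycolysis (1.59 times random; permutation test, adjusted p = 0.303), fatty acid oxidation (1.76; 0.144), ribosomal proteins (1.88; 0.081), pluripotency (0.341; 0.081) and kidney (0.564; 0.384). With flanks of 100 kb the calls for fatty acid oxidation (1.53; 0.0659), kidney (0.655; 0.202) and both Hox lists were lost.

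Start sites marked in only 1 pool were too few per list for a test toward replicate 2. Of the T cell and thymus list, 0 genes had a TSS peak in replicate 1 only and 6 in replicate 2 only, and the lung list had 0 and 6 as well. The genes, chosen after their values were seen apart from Nkx2-1 and Epcam, were Cd3d, Cd3e and Cd3g, subunits of the T cell receptor complex, Rag2, a recombinase subunit, and Foxn1 and Psmb11, of thymic epithelium. In the lung list they were Nkx2-1, Foxa1, Foxa2 and Sox2, airway and lung factors, and the epithelial adhesion genes Epcam and Cdh1. Among other genes, 32.9% of single-replicate start sites were in replicate 1, and neither split passed (exact binomial p = 0.187, adjusted p = 1 for each). No list had more than 6 such genes, and 0 against 6 is the most extreme split toward replicate 2, so 0 of 27 lists could have reached a p under 0.05 in that direction. Toward replicate 1, 10 lists could have. That 0 lists passed, and 0 had an unadjusted p under 0.05, therefore says nothing about excess in replicate 2. With equal numbers of top peaks, or with a fold of at least 4, 1 list had an unadjusted p under 0.05 and 0 passed.

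Some of the longest stretches of distal acetylation lay at heart genes. Distal peaks, 45963 or 64.3% of the replicated list, formed 18445 domains, of which the largest 5% (923) held 44.2% of summed width times fold. The largest lay at Tns1, a focal adhesion protein, on chromosome 1 from 73902536 to 74084972 (mm10), with 46 peaks over 182 kb. The next lay in Msi2, an RNA-binding protein, on chromosome 11 from 88359095 to 88703782, with 93 peaks. The domain of Myh7 on chromosome 14 from 54981106 to 55010566 covered 27.4 kb with 6 peaks, and the peak at its left end, 18.3 kb wide, also covered the Myh7 start. That peak had its summit over 2.5 kb from any TSS, so the Myh7 TSS fold of 37.0 was not measured at the start itself. Within the bounds of the domain replicate 1 had 27.4 kb and replicate 2 had 25.8 kb covered. The fourth lay at Rbm20, a splicing factor of titin, on chromosome 19 from 53648014 to 53831595, with 64 peaks. The others of the 15 largest were nearest to Grb10, Myh9, Lrrc74a, Pkig, 2310022B05Rik, Lrrfip1, Hspg2, Cxxc5, Mical2, Sipa1l2 and Irf2bp2. Genes were assigned by the distance from the middle of the domain to the nearest TSS alone, which was 58.7 kb for Msi2, 53.5 kb for Rbm20, 63.4 kb for Lrrc74a and 73.1 kb for Irf2bp2.

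Of 8286 genes nearest to any domain, 803 were nearest to one of the largest 5%. Cardiac transcription factors were among them in 14 of 28 cases (50%, against 9.55% of other genes; adjusted p over 26 lists = 1.65e-06). They included Hand2 (rank 45), Gata4 (46) and Nkx2-5 (108), and Tbx20 and Tbx5 at lower ranks. Calcium and ion channel genes were in 11 of 25 cases (0.000107), including Ryr2 and Pln, signalling genes in 11 of 26 (0.000113), including Hes1 and Smad7, and sarcomere genes in 7 of 23 (0.0311), including Myh7, Myl2 and Myl7. Those 4 lists passed and the other 22 did not, endothelium among them at 4 of 24 (0.925). Unlike the test of covered sequence, this comparison was not matched on gene length, nor on the number of domains nearest to a gene. Endothelium passed when domains were ranked by base pairs (odds ratio 4.90 against 2.05) or made from the pooled list (3.90; adjusted p 0.00645 to 1 over 6 alternatives). Of the 15 genes named, 7 remained among the 15 largest with replicate 2 alone, 10 with replicate 1 alone, 8 without stitching and 5 with ranking by base pairs.

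**Figure D3:**
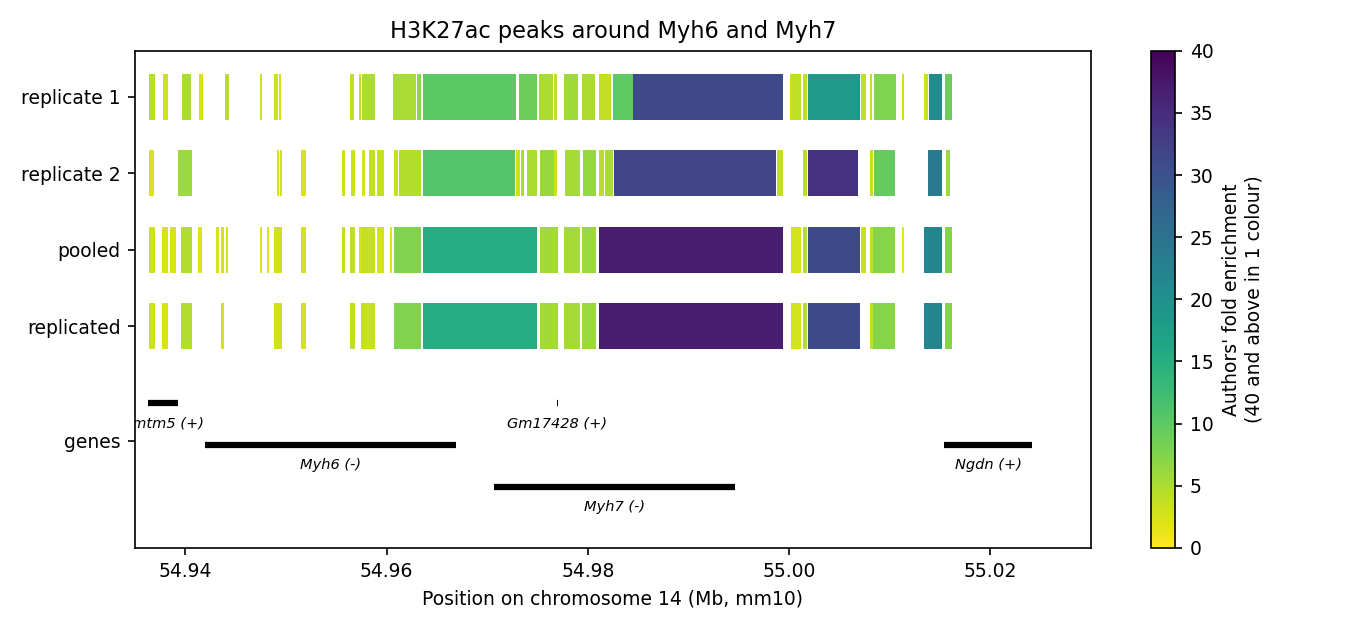
Peaks of the 4 lists on chromosome 14 from 54935000 to 55030000 (mm10), drawn by position and fold enrichment, with the annotated genes. The tallest replicated peak, with a fold of 37.0 and its summit over 2.5 kb from any TSS, covers the start of Myh7. There the folds are 31.3 in replicate 1 and 31.7 in replicate 2, where a peak from 55001912 to 55006865 is taller at 34.1.

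Motifs of MEF2, TEAD, ETS and AP-1 factors were more frequent at distal peaks than beside them, relative to rearranged motifs. The TEAD motif, of the Hippo pathway, was present in 16.7% of 45958 peak windows and 11.5% of 69757 flank windows (log2 ratio 0.54). The ETS motif, of endothelial and other factors, was present in 17.6% and 13.0% (0.43), the AP-1 motif in 11.1% and 8.58% (0.37), and the MEF2 motif, of muscle factors, in 9.99% and 8.85% (0.18). For each of these, 0 of 100 rearrangements gave as high a ratio (permutation test, adjusted p = 0.0396 over 16 motifs, resting on the smallest p that 100 rearrangements can give). The median rearranged MEF2 motif had a log2 ratio of -0.78, and windows at peaks held 47.9% GC against 44.2% in flanks. The MEF2 log2 ratio itself was small and varied: 0.01 with replicate 2 alone, 0.12 with replicate 1 alone and 0.04 with the pooled list, each still above its rearrangements. With a replicate left out the other 3 ranged from 0.33 for AP-1 to 0.50 for TEAD. The other heart motifs did not pass. NKX2-5 had a log2 ratio of 0.03 with 1 rearrangement as high (0.0634), MEIS 0.31 with 6 (0.185), ERR 0.56 with 9 (0.226), GATA -0.07 with 13 (0.277), SRF 0.08 with 29 (0.475), the HAND E-box 0.02 with 70 (0.803) and TBX -0.22 with 74 (0.803). Of 5 control motifs (HNF4, HNF1, OCT4, RFX and p53), 0 passed, with 19 to 84 rearrangements as high. The calls for the 4 motifs were lost with windows of 200 bp or 1000 bp and with a fold of at least 4 (adjusted p 0.0317 to 0.453 over all alternatives), and in 200 bp windows the MEF2 log2 ratio was -1.11.

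**Figure D4:**
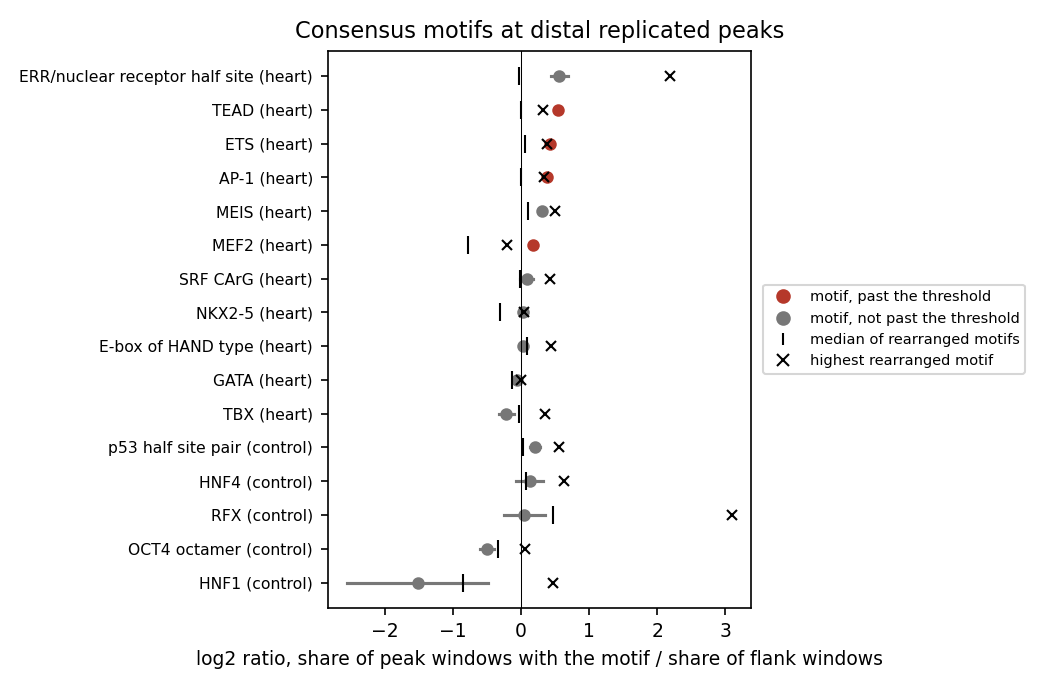
Log2 ratio of the share of windows with each motif at distal peaks to that in flanks, with the spread of its rearrangements. MEF2 (0.18), TEAD (0.54), ETS (0.43) and AP-1 (0.37) lie above all 100 of their rearrangements.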

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

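No test in this part was chosen after the results were seen. Peaks on unplaced or unlocalised sequence were left out of every comparison, and the lists nevertheless held some: 6 in replicate 1, 7 in replicate 2, 6 in the pooled list and 6 in the replicated list. They drew attention as signal in data that the comparisons do not use. The 6 replicated peaks lay on 5 sequences, with a median fold of 4.92 and a highest fold of 57.6. No explanation was tested for them.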

How the results depend on the processing

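All alternatives were chosen before the results were seen, except for 50% of the replicated peak as overlap and 1 gene per locus, which were chosen after seeing the data. Of 94 alternatives for the main answers, 79 kept the direction and the side of the threshold, or for counts stayed within 1.5 times, or for shares without a test within their 95% interval. Of 1249 alternatives in all, 3 reversed, counted only where either value passed its test. A further 38 values of lists, with no call on either side, also lay across 1 from their main value, such as lung genes at promoters with replicate 2 alone (1.10). Sharing stayed between 47.0% and 77.6% for replicate 1 and between 41.3% and 73.9% for replicate 2, each above its shifts, and the promoter share between 21.2% and 38.7%. The share of pooled peaks in the replicated list was 93.5% with a -log10 q of at least 5 and 99.9% with a fold of at least 4, against 61.4%. The share found in both replicates was 56.6%, 77.1% and, with an overlap of 1 bp, 86.4%, and with 50% of the replicated peak 72.5%, against 86.0%. The q and fold thresholds were applied to the replicate lists as well, where they kept a smaller share of peaks. With a fold of at least 4 the exon share was 3.30% and the intron share 38.0%, both on the other side of their shifts. Of lists around genes, a flank of 100 kb left 2 lower against 4. Distal peaks alone left 5 higher against 9 and 2 lower, with anterior Hox genes at 0.601 times random. With 1 gene per locus 8 were higher and 3 lower, and both Hox calls were lost. Of the 15 domain genes, 8 remained among the 15 largest without stitching, 5 with ranking by base pairs, and 7 to 10 with a replicate left out. Heart motifs passing fell from 4 to 0 with windows of 200 bp (log2 ratios: MEF2 -1.11, TEAD 0.40, ETS 0.27, AP-1 0.10), to 0 with 1000 bp (0.25, 0.44, 0.34 and 0.29 in that order) and to 0 with a fold of at least 4 (0.42, 0.61, 0.43 and 0.42). With a -log10 q of at least 5 the NKX2-5 motif passed with a log2 ratio of 0.028. Motif direction is judged against rearranged motifs, so MEF2 at -1.11 does not count as reversed. With 16 motifs and 100 rearrangements, a call needs several motifs at the smallest p, so the loss of a motif can end the calls of the others by construction; for the rest the cause was not tested. Of lists at promoters, 10 to 11 were higher and 8 to 12 lower under 7 alternatives, and 123 to 132 of the 133 named genes kept the presence or absence of a TSS peak. Of named fold values under alternatives, 314 lay within 1 SD of the replicated-list fold and 100 did not. That SD was taken over the 2 replicate folds of the gene, so it is a rough yardstick. Unknown depth limits what the absence of a peak can show.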

Other observations

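All tests in this part were chosen after the results were seen. Start-site peaks of 7 lists were wide, 4 of them by the most. Among the 12489 genes with a replicated TSS peak, random lists had a mean width of 1.72 kb, while sarcomere genes had a mean of 5.93 kb (SD 4.25, 28 genes), cardiac transcription factors 5.35 kb, signalling genes 5.02 kb and calcium and ion channel genes 3.77 kb. Among the widest 5% (625 genes, 4.23 kb or more) were 14 of 28 sarcomere genes, 12 of 25 signalling genes, 11 of 28 cardiac factors and 10 of 25 calcium and ion channel genes (Fisher exact tests, adjusted p from 2.58e-10 to 8.71e-07 over 23 lists). Glycolysis (6 of 19; Fisher exact test, 0.00109), endothelium (6 of 29; 0.0104) and fatty acid oxidation genes (5 of 25; 0.0234) passed as well. The widest, named after their values were seen, were Notch1 at 18.4 kb, a receptor of endocardium and endothelium, Myh7 at 18.3 kb and the sodium pump gene Atp1a1 at 18.0 kb. The strongest by fold, also named after their values were seen, were the histone methyltransferase gene Kmt5b at 63.3 and the transcription factor gene Sp3 at 62.5. Mean fold was raised too for most of these lists. Against random genes it was 1.63 times for signalling, 1.54 for glycolysis, 1.48 for cardiac factors, 1.45 for the sarcomere and 1.39 for fatty acid oxidation (permutation tests, adjusted p from 0.0023 to 0.0109). It was 1.07 times for calcium and ion channel genes (permutation test, adjusted p = 0.617) and lower for endothelium at 0.598 (permutation test, 0.0023). None of the 23 lists passed for the strongest 5% by fold, and 1 (sarcomere, 5 of 28, exact p = 0.0116) had an unadjusted p under 0.05. Of the widest 625 genes, 116 (18.6%) were also among the strongest 5%.

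Replicated TSS peaks lay at 7 of 10 anterior Hox genes of clusters A and B, at 0 of 5 of clusters C and D and at 0 of 17 posterior genes. The split by cluster was drawn from where peaks were seen, and genes of a cluster are linked, so no test is given. None of 7 globin genes had a replicated TSS peak, against 4 of 14 other erythroid genes. On the X chromosome 382 of 948 genes (40.3%) had one, against 12105 of 20753 (58.3%) on autosomes, with median folds of 10.1 and 13.1. Single autosomes ranged from 47.8% (chromosome 7) to 66.1% (chromosome 12), and no p is given, since genes of a chromosome are not independent.

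Coverage around genes was compared between the replicates with the 100551 strongest peaks of each. Relative to random lists (mean log2 ratio of replicate 2 to replicate 1 from 0.04 to 0.05), 6 lists had more covered sequence in replicate 2 and 2 had more in replicate 1. Anterior Hox genes had 14.7 kb in replicate 2 and 6.50 kb in replicate 1 (mean log2 ratio 0.71), T cell and thymus genes 6.42 and 5.04 kb (0.43; permutation tests, adjusted p = 0.0018 each over 27 lists, resting on the smallest p that 10000 random lists can give). Posterior Hox genes (0.31; 0.0027), smooth muscle (0.22; 0.0139), fibroblast (0.20; 0.0099) and lung genes (0.20; 0.0236) were the others. Calcium and ion channel genes (-0.14; 0.0018) and sarcomere genes (-0.09; 0.0099) had more in replicate 1, and endothelial genes had 0.00 and hepatocyte genes 0.04, neither passing. These values count start-site peaks, and neighbours such as Hox or Cd3 genes separately. Without start-site peaks, 4 lists had more in replicate 2 and 1 had more in replicate 1, with T cell and thymus genes at 0.26 (permutation test, adjusted p = 0.0378) and lung genes at 0.04 (0.980). With 1 gene per locus in addition, 0 lists passed either way, with fewer members in some lists and ratios of like size in most. Calcium and ion channel genes kept -0.14 with the same 26 genes (permutation test, adjusted p = 0.0936) and fibroblast genes had 0.21, so the lost calls do not show that the differences are absent.

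For the T cell, thymus and lung genes with a start-site peak in replicate 2 only, 2 explanations were tested. With all peaks the 2 lists together split 0 against 12 (exact binomial p = 0.0117 against 33.2% in replicate 1 for other genes), a test on genes pooled because they showed the split. It counts the neighbouring genes Cd3d, Cd3e and Cd3g as separate, as does any split below that holds them, so p can be too small. A longer peak list in replicate 2 could give this split. With equal numbers of peaks the split was 2 against 12 (exact binomial p = 0.0544 against 41.6%), with 0 against 6 for lung genes (exact p = 0.0454) and 2 against 6 for T cell and thymus genes (exact p = 0.483). Both lean toward replicate 2 on few genes, so the test does not decide and list length stays open. Thymus and lung tissue in the replicate 2 pool stays open too: 0 of the 2 lists had more covered sequence in replicate 2 past the threshold, without start-site peaks and with 1 gene per locus. There T cell and thymus genes had 0.26 (permutation test, adjusted p = 0.0936) and lung genes 0.04 (0.972). The surfactant genes Sftpc and Sftpb and the thymocyte genes Cd8a, Cd4 and Ptcra, chosen after their values were seen, had no start-site peak in either replicate. Expression of these genes in lung and thymus at this stage was not measured, so their absence does not count against such tissue. Cd3d had a fold of 5.21 in replicate 2. Of the 41 genes, 12 had a start-site peak in both replicates and 2 are in another list too; no biological explanation was tested, and other dissection or developmental differences between the pools stay open.

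For wide start-site peaks of heart genes, 2 technical explanations were tested on the 4 heart lists with the most. The lists of cardiac factors and of signalling share Hey1, Hey2, Tead1 and Tbx20, so the 4 lists are not independent. Taller peaks are called wider (Spearman rho of width and fold 0.681 across genes, which are not independent replicates), yet against random genes matched on fold, 4 of 4 lists were still wider, by 2.04 to 2.63 times. Against random genes matched on the number of start sites, 4 of 4 lists were wider too. Both tests argue against these as the whole cause, and the authors' peak settings stay open. Width beyond fold was not particular to these 4 lists. Matched on fold, endothelium (2.20 times), fibroblasts (2.02), anterior Hox (1.99), smooth muscle (1.65), skeletal muscle (1.63) and glycolysis (1.52) passed as well. Fatty acid oxidation did not (1.29; permutation test, adjusted p = 0.0897). No biological explanation was tested, since the series holds 1 group.

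Some motifs at distal peaks were less dense within 100 bp of the summit of acetylation than over 100 to 500 bp as a whole. Within 100 bp of the summit against 100 to 500 bp, log2 ratios of motif density were -1.57 for MEF2, -0.21 for ETS, -0.17 for TEAD and -0.25 for AP-1, the motifs that passed. Density did not rise steadily outward: for TEAD and ETS it was highest at 100 to 300 bp, and in the outermost 100 bp (311 and 331 per Mb) it was below that within 100 bp. Within 100 bp TEAD (326 against 249 per Mb), ETS (340 against 288) and AP-1 (200 against 183) were still denser than in flanks, and MEF2 (91.5 against 196) was not. Of the other heart motifs, SRF had -0.53 with 0 of 100 rearrangements as low, GATA -0.43 with 8, NKX2-5 -0.21 with 85, ERR 0.25, TBX 0.08, MEIS 0.07 and the HAND E-box 0.07. Of the control motifs, OCT4 had -0.48 with 38 of 100 as low, RFX -0.23 with 21, HNF4 0.10 and p53 0.06. HNF1 had no match within 100 bp and few elsewhere, with 2 as low. GC content fell from 49.7% within 100 bp to 45.1% in the outermost 100 bp. Base composition at the summit could give this: for MEF2, 13 of 100 rearrangements had as low a ratio, so it remains open. It is argued against for ETS (0 of 100) and TEAD (1 of 100), and the 3 of 100 for AP-1 lie too near the limit to decide. No biological explanation was tested.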
